A study of Homo sapiens with 12 samples.

How the data were processed

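Total RNA of 6 HepG2 cultures, 3 per vessel, was labelled and hybridized in duplicate to Affymetrix human expression arrays. The deposited values are linear intensity signals per probe set, which the authors computed with MAS5 and scaled so that each array had about the same trimmed mean, near 500 (499.85 to 499.86 in the values). The version, detection calls and background settings of MAS5 are not stated, so low signals were handled by a filter instead.

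Signals were log2-transformed with no offset. A rule written before the data were examined asked for quantile normalization where array medians differed by more than 0.2 on the log2 scale, and they did, so the 12 arrays were quantile normalized. The values as deposited then became an alternative. The 68 control probe sets were left out, and probe sets with a mean log2 signal at or above the 40th percentile (5.40, a signal of 42.1) were kept, 13329 in all. A group mean below that limit is treated as a bound, and folds against it are given as at least. The 2 arrays of each culture were averaged, so that the culture was the replicate. Groups were compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with an intensity trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Residual degrees of freedom were 4 and the prior added 10.6. Nothing in the labels pairs plate and VECELL cultures of the same number, and their residuals correlated at -0.002, -0.005 and -2.52e-04 across genes, so no block was used.

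Probe sets were named by their single gene symbol, with gene names checked against the GRCh38.p14 gene table. Of 22283 probe sets 19071 had 1 symbol, 1043 had several and 2169 had none. The probe set with the highest mean signal represented each gene. Some genes had other kept probe sets of which none passed the threshold, among them *GSTA1*, *CYP3A4*, *IL1RN*, *HGD*, *PLIN2*, *ALDH4A1*, *ARG2*, *RXRA*, *HSPH1* and *NDUFB2*. The 43 gene lists, fixed before the data were examined, held 1385 genes, of which 1013 had a kept probe set. The 42 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, with adjustment over lists. Of these, 13 were called higher and 8 lower. The 8 that were also called with an estimated correlation were G2 and mitosis (adjusted p = 0.0473), hypoxia (0.0144), glycolysis (0.0252), metallothioneins (0.0252), mesenchymal genes (0.0373), immediate early genes (0.0473), YAP and TEAD targets (0.0473) and the unfolded protein response (0.0473). For 3 lists that lost their call the estimate was below the preset value. These were integrins and focal adhesion (0.0016), fetal liver, progenitor and tumour markers (-9.29e-04), and gluconeogenesis and glycogen (-0.0022). A higher correlation between genes was therefore not the reason there. The self-contained test fry, which does not compare a list with other genes, called 34.

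Named genes followed a rule fixed before the data were examined. It took the 10 largest increases and 10 largest decreases among genes past the threshold whose cultures did not overlap and whose higher mean reached the median of the kept probe sets. It added for each list up to 2 genes per direction with the largest changes past the threshold, or the gene with the smallest p where none passed, and a short set of liver and culture markers. Markers of that set with no probe set of a single symbol, 3 in all, are not analysed here. The rule gave 149 genes.

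The procedure was tested on simulated data with changes planted at known folds in 3 cultures per group. It recovered 44.6% of changes of 1.5-fold, 59.4% of 2-fold and 93.4% of 4-fold, and 5.81% of its calls had not been planted. With no change planted it called 0 probe sets and 0 lists. The simulated noise was independent between probe sets, so this could not show lists called falsely through correlated genes. In the data, wrong splits of the cultures called up to 14 lists. Those splits were uneven in vessel, so part of the vessel difference remained and their lists do not measure false calls. Besides a shifted list, 200 changed probe sets were planted, against 20.8% of 13329 called in the data, so the recovery rates need not hold there.

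Alternatives tried were the values as deposited, median centring, an offset of 12.9 before the log, no filter and a filter at the 60th percentile, and eBayes without the trend. Others were each hybridization alone, all 12 arrays with a random culture effect (statmod 1.5.0), a replicate block, leaving out each culture, other thresholds, other ways to summarise a gene, an estimated correlation, and fry. The fit to all 12 arrays also held a term for the hybridization round, and its lists were tested by a form of camera on the fitted t statistics. Its correlation between arrays of 1 culture was -0.014, so list calls that changed there cannot be credited to the random effect alone. Leaving out the 3 arrays with the highest medians, and leaving out the hypoxia genes shared with the glycolysis and ATF4 lists, were added after the data were seen.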

Results

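Messenger RNA was profiled in HepG2 cells, an established human liver tumour line that keeps part of the hepatocyte programme, after 3 days in 1 of 2 vessels. In 1 group 3 cultures grew on a normal culture plate, and in the other group 3 cultures grew on VECELL, a vessel that the study describes as a three-dimensional culture system. Each RNA was hybridized to 2 arrays, which gave 12 arrays of 22283 probe sets. The median log2 signal per array ran from 6.50 to 6.80 before normalization, and the number of arrays limits the precision of every value. The comparison asked which functions of HepG2 cells differ between the vessels.

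On VECELL, genes of the hypoxia response, glycolysis, the metallothioneins, the mesenchymal list and the immediate early list rose, and genes of mitosis and the unfolded protein response fell. *MT1E*, which encodes a metal-binding metallothionein, was 8.26-fold higher on VECELL, and *HAMP*, which encodes the iron hormone hepcidin, was 7.64-fold higher. *GSTA1*, a glutathione transferase of liver, was 7.26-fold lower on VECELL by its brightest probe set, while its other kept probe set did not pass the test. By their brightest probe sets albumin and alpha-fetoprotein, *ALB* and *AFP*, had log2 fold changes of -0.11 ± 0.04 and -0.13 ± 0.05 (SE, n = 3 cultures per group) after quantile normalization, which gives every array the same values at the top of the scale, where both lie. With the values as deposited they were called lower, at -0.24 (adjusted p = 0.00696) and -0.27 (adjusted p = 0.00311). Both other *ALB* probe sets were lower past the threshold after quantile normalization (-0.88 and -0.34).

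Of 13329 probe sets tested with limma, 1389 were higher and 1382 were lower on VECELL at an adjusted p under 0.05, together 20.8%. A change of at least 2-fold was more often upward, with 268 probe sets higher and 57 lower. Counted by gene, 892 of 8008 genes were higher and 920 were lower. The median absolute log2 fold change of the probe sets past the threshold was 0.44. The 3 VECELL cultures and the 3 plate cultures did not overlap in 36.9% of the probe sets tested, where chance gives 10%. The first principal component separated the vessels and held 43.4% of the variance. Without VECELL replicate 2 the counts were 901 higher and 885 lower, and with the second hybridization alone they were 724 and 650. The 3 cultures of a vessel differed from each other about as much as 2 arrays of 1 culture did, so the errors given here mainly describe array noise. The ratio of the mean variances was 0.978 over all probe sets, where weak and noisy probe sets weigh most, and 0.955 to 1.07 over bands of signal.

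Under the naming rule, 10 genes stood for the largest increases among genes of at least median signal. *TFF1*, a secreted trefoil peptide, had a log2 signal of 5.29 ± 0.05 on the plate and 8.43 ± 0.36 on VECELL (SD, n = 3). Its plate signal lay below the detection filter, which makes the increase at least 8.21-fold. *MT1E* rose from 10.56 ± 0.18 to 13.61 ± 0.05, with an adjusted p of 1.81e-12. *HAMP* rose from 8.70 ± 0.03 to 11.64 ± 0.15, with an adjusted p of 6.70e-12. *CCN1*, a matricellular protein, rose by 2.57 ± 0.18 on the log2 scale (SE). *FILIP1L* rose by 2.44 ± 0.14, the metallothionein-like *MT1HL1* by 2.40 ± 0.10, and the LIM-domain cofactor *FHL2* by 2.38 ± 0.12. The probe sets of *MT1E* and *MT1HL1* are of a kind that can match several transcripts. *TMSB4X*, which encodes the actin-binding peptide thymosin beta-4, rose by 2.38 ± 0.19. The lectin gene *LGALS3* rose by 2.32 ± 0.10, and *TNS1*, whose product links integrins to actin, rose by 2.31 ± 0.14.

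Under the same rule, 10 genes stood for the largest decreases. *GSTA1* had a log2 signal of 12.20 ± 0.28 on the plate and 9.34 ± 0.09 on VECELL (SD, n = 3), with an adjusted p of 1.78e-10. The pepsinogen gene *PGC* changed by -2.13 ± 0.11 on the log2 scale (SE). *UGT2B4*, which glucuronidates bile acids, changed by -2.02 ± 0.19, and *HPX*, which encodes the haem carrier hemopexin, by -2.01 ± 0.14. *DIO1*, a thyroid hormone deiodinase, changed by -1.79 ± 0.11 and the calcium-binding *SCGN* by -1.75 ± 0.10. *DGAT1*, which makes triglycerides, changed by -1.64 ± 0.13. The collagen gene *COL2A1* changed by -1.48 ± 0.10, the bile acid enzyme gene *AKR1D1* by -1.36 ± 0.10, and the organic anion transporter gene *SLCO4C1* by -1.30 ± 0.17.

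**Figure D1:**
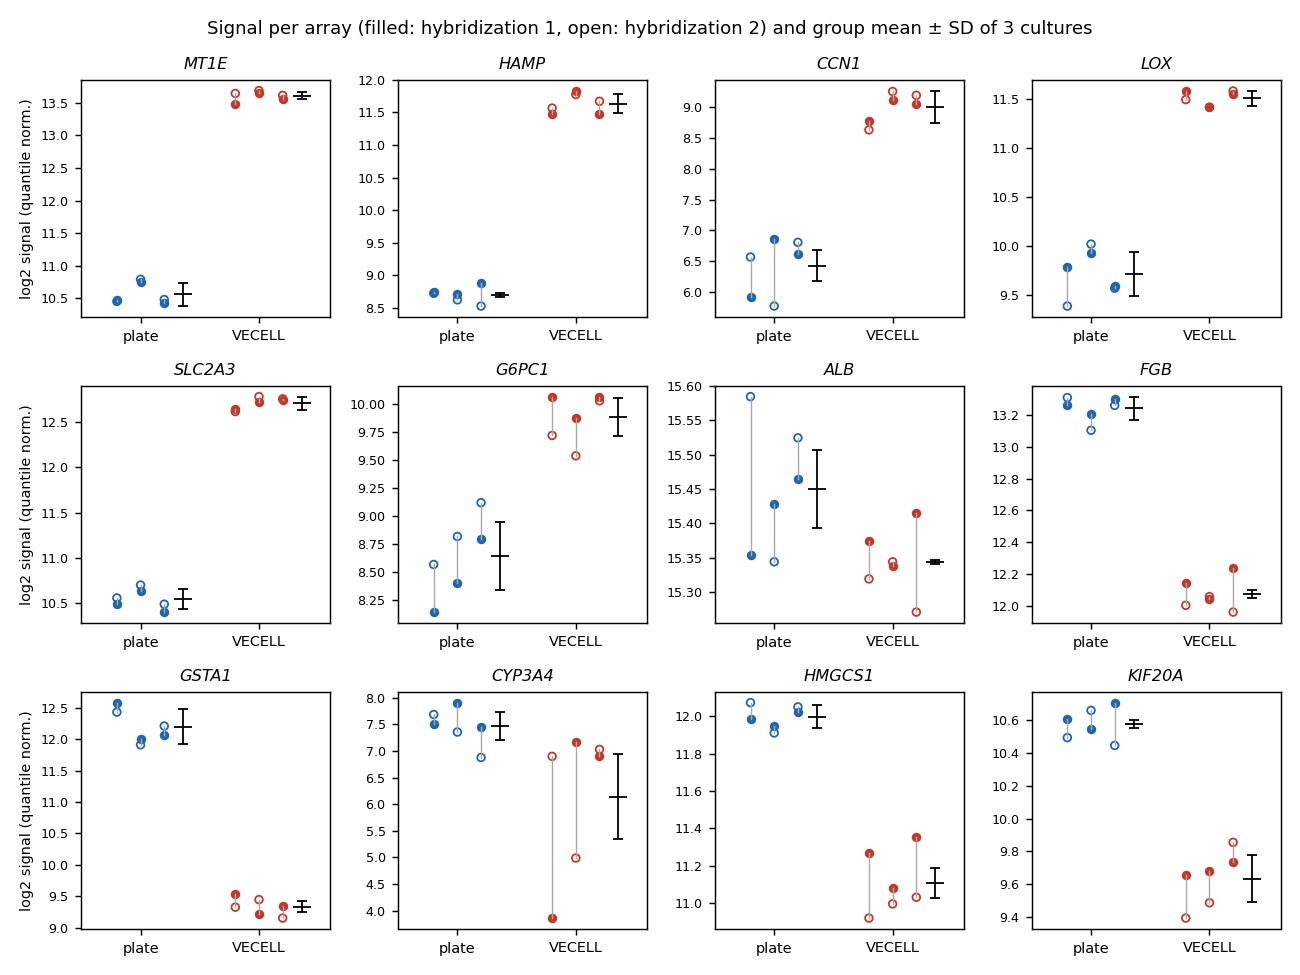
Log2 signal after quantile normalization (vertical axis) of 12 named genes in each array, with the plate cultures in blue and the VECELL cultures in red. Filled and open points are the first and second hybridization of 1 culture, joined by a line, and black bars give the mean and SD of 3 cultures. The scales differ between genes, and *ALB* spans a far narrower range than *MT1E* or *GSTA1*.

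Genes that respond to low oxygen rose on VECELL as a group. Of 31 measured hypoxia response genes, 25 rose and 0 fell, or 28 and 0 adjusted over the list alone, with a median log2 fold change of 0.69 (camera adjusted p = 6.67e-22). *LOX*, which cross-links collagen, rose by 1.79 ± 0.10 (SE, n = 3 per group), and *EGLN3*, an oxygen-sensing prolyl hydroxylase, rose by 1.75 ± 0.24. Glycolysis genes rose too, 14 of 19 with 0 falling, or 16 and 0 adjusted over the list alone (median 0.44, adjusted p = 2.89e-12). The glucose transporter gene *SLC2A3* rose 4.49-fold. The phosphofructokinase gene *PFKP*, below the detection filter on the plate, rose at least 3.28-fold, a call that ended with the second hybridization alone (adjusted p = 0.0958). All 6 metallothionein genes of the list rose, and *SLC30A1*, the zinc exporter in the same list, changed by -0.36 ± 0.08 (list median 1.79, adjusted p = 8.71e-12; 6 up and 1 down adjusted over the list alone). *MT1X* rose 4.79-fold. The 9 probe sets of these 6 genes that passed the filter are all of a kind that can match several transcripts.

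Mesenchymal, immediate early and YAP and TEAD target genes rose on VECELL. In the mesenchymal list 11 of 19 genes rose and 1 fell, or 12 and 1 adjusted over the list alone (median 0.67, adjusted p = 1.09e-07). Those that rose included *S100A4*, *S100A6*, *S100A10*, *S100A11*, *ANXA2* and *ANXA3*, which also belong to a group of S100 proteins and annexins described further below. *SPARC* fell, and the mesenchymal marker *VIM* lay below the detection filter in both vessels. The receptor tyrosine kinase gene *AXL* rose 4.99-fold and *S100A11* 3.95-fold. Of the immediate early genes 13 of 22 rose and 0 fell, with the same counts adjusted over the list alone (median 0.46, adjusted p = 3.53e-07), and *IER3* rose 3.59-fold. Among YAP and TEAD targets 7 of 14 rose and 1 fell, or 8 and 1 adjusted over the list alone (median 0.71, adjusted p = 1.92e-05). *ANKRD1*, below the detection filter on the plate, rose at least 7.15-fold, and the survival gene *BIRC5*, which also belongs to mitosis, changed by -0.63 ± 0.07. Without the probe sets that can match several transcripts the YAP and TEAD list was not called (adjusted p = 0.0523).

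For 5 further lists the call as higher was lost with an estimated correlation. Among TGF-beta targets 7 of 15 rose and 0 fell, or 10 and 0 adjusted over the list alone (median 0.50, adjusted p = 6.60e-06, but adjusted p = 0.0552 with an estimated correlation). *ID1* rose 2.49-fold and *ID3* 1.59-fold. Both, with *ID2*, *SMAD7* and *BAMBI*, are also among the genes that rose in the group of BMP-SMAD targets described further below. Actin cytoskeleton genes gave 13 higher and 2 lower of 34, or 15 and 2 adjusted over the list alone (median 0.21, adjusted p = 1.92e-05, but adjusted p = 0.153 with an estimated correlation). Integrin and focal adhesion genes gave 7 higher and 0 lower of 22, or 8 and 0 adjusted over the list alone (median 0.19, adjusted p = 0.00107, but adjusted p = 0.0655 with an estimated correlation). The collagen receptor gene *ITGA2* rose 2.69-fold. Junction and polarity genes gave 10 higher and 1 lower of 27, with the same counts adjusted over the list alone (median 0.19, adjusted p = 0.00310, but adjusted p = 0.157 with an estimated correlation). Their median was 0.08 without VECELL replicate 3 and 0.00 without plate replicate 1, with the list still called. The keratin gene *KRT19* rose 3.30-fold and the desmosome gene *DSP* 1.79-fold. Fetal liver, progenitor and tumour markers gave 9 higher and 2 lower of 19, or 10 and 3 adjusted over the list alone (median 0.20, adjusted p = 0.00107, but adjusted p = 0.0655 with an estimated correlation), and *BEX1* changed by -0.96 ± 0.07 and *DLK1* by -0.22 ± 0.05. The array's own actin control probe sets were 1.25-fold and 1.34-fold higher on VECELL.

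For 2 lists of glucose and amino acid metabolism the call as higher was likewise lost with an estimated correlation. Of 23 gluconeogenesis and glycogen genes 10 rose and 1 fell, or 11 and 2 adjusted over the list alone (median 0.23, adjusted p = 4.51e-04, but adjusted p = 0.0581 with an estimated correlation). The coactivator gene *PPARGC1A* rose 2.44-fold and *G6PC1*, the glucose-6-phosphatase that releases glucose, rose 2.36-fold. In the ATF4 and amino acid list 20 of 36 genes rose and 1 fell, or 24 and 2 adjusted over the list alone (median 0.28, adjusted p = 2.44e-07, but adjusted p = 0.148 with an estimated correlation). Asparagine synthetase, encoded by *ASNS*, rose 2.10-fold, and the lipoprotein receptor gene *VLDLR* rose 1.89-fold.

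Genes of mitosis fell on VECELL. Of 56 G2 and mitosis genes 43 fell and 0 rose, or 49 and 0 adjusted over the list alone (median -0.42, adjusted p = 6.38e-22). The kinesin gene *KIF20A* was 1.92-fold lower and the centromere histone gene *CENPA* 1.80-fold lower. *MKI67*, a common proliferation marker, had a log2 fold change of -0.14 ± 0.11 by its brightest probe set, which did not pass the test (adjusted p = 0.399), while 1 of its 3 others was lower past the threshold (-0.48, adjusted p = 0.0314). S phase and DNA replication genes gave 10 lower and 1 higher of 51, or 11 and 1 adjusted over the list alone (median -0.14, adjusted p = 0.00857, but adjusted p = 0.157 with an estimated correlation). *TYMS* was 1.42-fold lower. *RFC5* was 1.49-fold lower by its brightest probe set, while another of its probe sets changed in the opposite direction past the threshold.

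Of 4 lists of lipid synthesis and protein turnover, the unfolded protein response kept its call as lower with an estimated correlation. In the cholesterol list 12 of 19 genes fell and 0 rose, or 14 and 0 adjusted over the list alone (median -0.54, adjusted p = 6.26e-09, but adjusted p = 0.148 with an estimated correlation). The sterol isomerase gene *EBP* was 2.04-fold lower and *HMGCS1*, which makes the precursor of mevalonate, 1.85-fold lower. Fatty acid and triglyceride synthesis genes gave 11 lower and 2 higher of 21, or 13 and 2 adjusted over the list alone (median -0.28, adjusted p = 0.00415, but adjusted p = 0.311 with an estimated correlation). *SCD* was 1.38-fold lower, whereas the lipid droplet gene *PLIN2* was 1.69-fold and *LPIN2* 1.75-fold higher. Without the probe sets that can match several transcripts this list was not called (adjusted p = 0.218). Of 26 unfolded protein response genes 15 fell and 0 rose, or 16 and 1 adjusted over the list alone (median -0.19, adjusted p = 1.92e-05), and *SDF2L1* was 1.71-fold lower. Proteasome genes gave 8 lower and 0 higher of 28, or 9 and 0 adjusted over the list alone (median -0.11, adjusted p = 4.13e-04, but adjusted p = 0.165 with an estimated correlation), and *PSMC3* was 1.39-fold and *PSMD1* 1.34-fold lower.

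Secreted liver proteins moved in both directions. Coagulation genes gave 8 lower and 2 higher of 19, or 9 and 2 adjusted over the list alone (median -0.30, -0.15 without plate replicate 2, adjusted p = 0.00403, but adjusted p = 0.278 with an estimated correlation). The fibrinogen chain gene *FGB* was 2.24-fold lower and plasminogen, *PLG*, 2.16-fold lower, while *PROS1* was 1.26-fold higher. Plasma protein genes gave 11 lower and 4 higher of 30, or 14 and 4 adjusted over the list alone (median -0.12, adjusted p = 0.00839, but adjusted p = 0.248 with an estimated correlation). Ceruloplasmin, *CP*, was 2.18-fold higher and haptoglobin, *HP*, 1.47-fold lower. With all 12 arrays and a random culture effect the plasma protein list was not called (adjusted p = 0.126), nor was it without the probe sets that can match several transcripts (adjusted p = 0.405). The brightest probe set of *ALB* did not pass the test (adjusted p = 0.102), while its 2 others, with far weaker signals, were lower past the threshold (-0.88, adjusted p = 0.000310, and -0.34, adjusted p = 0.0366). *AFP* did not pass the test (adjusted p = 0.0714). Without plate replicate 2 the brightest probe sets of both were called lower, at -0.14 (adjusted p = 0.0449) and -0.18 (adjusted p = 0.0189).

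**Figure D2:**
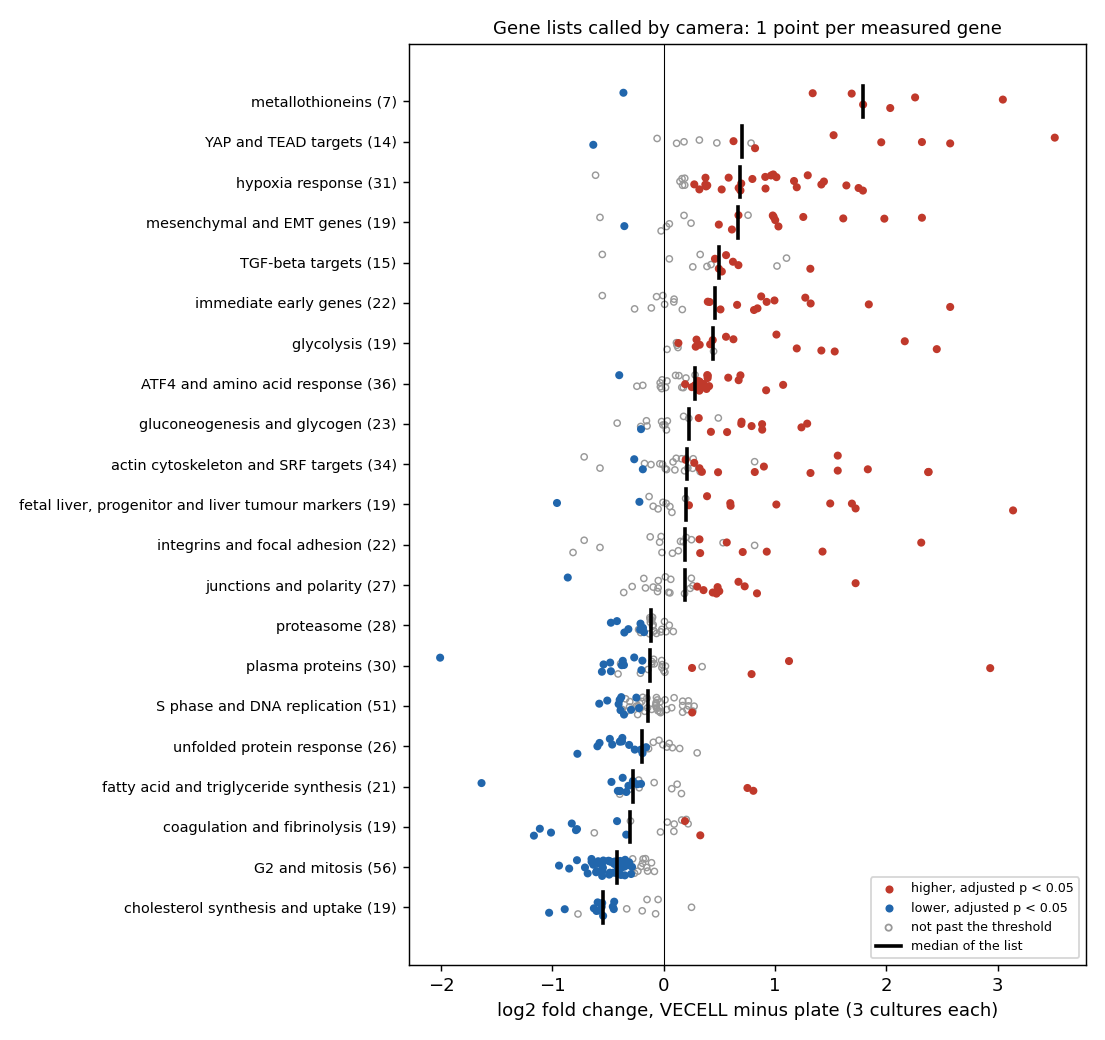
Log2 fold change, VECELL minus plate (horizontal axis), of each measured gene in the 21 gene lists called by camera, with the number of genes in brackets. Red and blue points are genes higher and lower past the threshold, open points did not pass it, and black bars are list medians, from 1.79 for metallothioneins to -0.54 for cholesterol synthesis.

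Lists of drug metabolism and transport were not called as a whole, while single members changed. Phase I genes gave 3 higher and 8 lower of 27, or 5 and 8 adjusted over the list alone (median -0.12, adjusted p = 0.175). *CYP1A1*, which oxidizes aromatic hydrocarbons, was 1.79-fold higher and *FMO5* 1.47-fold higher, whereas the carboxylesterase gene *CES1* was 2.04-fold lower. *CYP3A4*, the main drug-oxidizing cytochrome of adult liver, was 2.50-fold lower by its brightest probe set (adjusted p = 0.0111), with an SD of 0.80 between VECELL cultures. The other kept probe set of *CYP3A4* did not pass the test. The call of the brightest ended with the first hybridization alone (adjusted p = 0.139), the second alone (0.217), eBayes without the trend (0.0969) and without the 3 arrays with the highest medians (0.0960). *CYP1A2* did not pass the test (log2 fold change -0.28 ± 0.27, adjusted p = 0.518). *CYP2B6*, *CYP2E1*, the bile acid carrier gene *SLC10A1* and *VIM* lay below the detection filter in both vessels. *CYP7A1*, the rate-limiting enzyme of bile acid synthesis, lay below the filter on average, with log2 signals of 5.68 ± 0.17 on the plate and 1.31 ± 0.98 on VECELL (SD, n = 3). It was at least 1.22-fold lower against the filter limit (adjusted p = 5.83e-04 with no filter). Phase II genes gave 4 higher and 7 lower of 21, or 6 and 8 adjusted over the list alone (adjusted p = 0.256, 0.0254 with all 12 arrays and a random culture effect, and 0.0162 by fry), and *GSTZ1* was 1.51-fold and *MGST2* 1.33-fold higher. Hepatic transporters gave 1 higher and 3 lower of 17, with the same counts adjusted over the list alone (median -0.16, adjusted p = 0.260). *ATP8B1* was 1.48-fold lower and *ATP7B* 1.33-fold lower, and *ABCC2* did not pass the test (-0.18 ± 0.10, adjusted p = 0.214).

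Further liver lists were not called. Bile acid synthesis gave 1 higher and 5 lower of 12, with the same counts adjusted over the list alone (median -0.13, adjusted p = 0.101), and *CYP27A1* was 1.64-fold lower. That list was called lower by camera under 5 alternatives, at adjusted p from 0.0254 to 0.0366, among them without VECELL replicate 1 (adjusted p = 0.0340), and passed fry (adjusted p = 0.0245). Liver transcription factors gave 7 higher and 2 lower of 32, or 10 and 5 adjusted over the list alone (median 0.12, adjusted p = 0.107, 0.0366 with the stricter filter, and 0.0106 by fry), with *CEBPD* 2.11-fold higher and *NR2F6* 1.43-fold lower. Complement gave 3 higher and 5 lower of 19, or 4 and 7 adjusted over the list alone (median -0.07, adjusted p = 0.370). *C5* was 2.34-fold higher, *C8G* at least 2.71-fold higher, *C4BPA* 1.72-fold lower and *CLU* 1.55-fold lower. Urea cycle and amino acid catabolism gave 7 higher and 4 lower of 42, with the same counts adjusted over the list alone (median 0.04, adjusted p = 0.236), with *ALDH4A1* 1.97-fold and *ARG2* 1.71-fold higher and *HGD* 1.27-fold lower. *TAT* and *CPS1* did not pass the test, with log2 fold changes of 0.41 ± 0.21 and 0.24 ± 0.11. Fatty acid oxidation gave 3 higher and 6 lower of 30, or 4 and 7 adjusted over the list alone (median -0.04, adjusted p = 0.375), with *CPT1A* 2.48-fold and *ANGPTL4* 1.98-fold higher and *SLC25A20* 1.69-fold lower. Each of these calls ended in 1 hybridization round, that of *CPT1A* in the first (0.85, adjusted p = 0.0603) and those of *ANGPTL4* (0.52, adjusted p = 0.169) and *SLC25A20* (-0.59, adjusted p = 0.0683) in the second. Oxidative phosphorylation gave 6 higher and 6 lower of 56, or 6 and 8 adjusted over the list alone (median 0.00, adjusted p = 1.00), with *ATP5MC2* 1.26-fold and *NDUFV2* 1.22-fold higher and *NDUFA2* 1.32-fold and *NDUFB2* 1.29-fold lower. The median, mean and camera direction differed in sign for phase II, complement, fatty acid oxidation, oxidative phosphorylation and Wnt targets.

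Stress and signalling lists that were not called also held single changed genes. The acute phase and NF-kB list gave 4 higher and 6 lower of 19, or 5 and 6 adjusted over the list alone (median -0.20, adjusted p = 0.152, 0.00728 with all 12 arrays and a random culture effect, and 0.00165 by fry), with *IL1RN* 1.68-fold higher and *FGA* 1.77-fold lower. Interferon genes gave 3 higher and 10 lower of 29, with the same counts adjusted over the list alone (median -0.15, adjusted p = 0.264), with *IFITM2* 2.41-fold and *IFITM3* 2.00-fold higher and *IFI6* 1.76-fold lower. NRF2 targets gave 2 higher and 5 lower of 23, or 5 and 9 adjusted over the list alone (median -0.12, adjusted p = 0.256). *HMOX1* was 1.86-fold higher, *SLC7A11* rose by 0.58 on the log2 scale, and *GPX2* was 1.73-fold and *UGDH* 1.33-fold lower. Heat shock genes gave 3 higher and 5 lower of 16, with the same counts adjusted over the list alone (median -0.10, adjusted p = 0.264), with *SERPINH1* 1.57-fold higher and *DNAJA1* 1.46-fold and *HSPH1* 1.40-fold lower. p53 targets gave 1 higher and 6 lower of 22, with the same counts adjusted over the list alone (median -0.11, adjusted p = 0.157), with *GDF15* 1.58-fold higher and *PPM1D* 1.44-fold lower. Wnt targets gave 3 higher and 2 lower of 13, with the same counts adjusted over the list alone (median -0.02, adjusted p = 0.902), with *BMP4* 1.62-fold and *TBX3* 1.59-fold higher and *RHBG* 2.00-fold and *DKK1* 1.59-fold lower.

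Matrix, ribosome and lysosome lists were not called. Extracellular matrix genes gave 12 higher and 6 lower of 38, or 13 and 7 adjusted over the list alone (median 0.04, adjusted p = 0.107). That list was called higher by camera under 4 alternatives, at adjusted p from 0.0276 to 0.0445, and passed fry, which compares no list with other genes (adjusted p = 0.00302). The list median differed in sign between rounds, at -0.09 with the first hybridization alone (camera adjusted p = 0.302) and 0.17 with the second alone (0.0276). *HSPG2* was higher with both hybridizations averaged (adjusted p = 0.00181), but its log2 fold change was 0.70 with the second hybridization alone (adjusted p = 0.594), and its call ended without the 3 arrays with the highest medians (adjusted p = 0.103). *COL4A5* was 1.49-fold and *LAMC1* 1.39-fold lower, and *COL1A1* did not pass the test (0.31 ± 0.20, adjusted p = 0.327). Ribosomal protein genes gave 1 higher and 3 lower of 52, or 1 and 2 adjusted over the list alone (median 0.01, adjusted p = 0.560), with *RPL7* 1.22-fold higher and *RPL39* 1.14-fold lower. Ribosome biogenesis and MYC targets gave 3 higher and 4 lower of 33, or 4 and 4 adjusted over the list alone (median -0.05, adjusted p = 0.256), and *MRTO4* was 1.44-fold lower. Autophagy and lysosome genes gave 6 higher and 5 lower of 32, or 8 and 5 adjusted over the list alone (median 0.02, adjusted p = 0.769), with *WIPI1* 2.24-fold and *NPC1* 1.34-fold higher and *GLA* 1.88-fold and *NEU1* 1.63-fold lower.

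Markers of other cell types gave no list called by camera. Fibroblast markers gave 2 higher and 1 lower of 6, with the same counts adjusted over the list alone (median 0.14, adjusted p = 0.370), with *PDGFRB* 2.74-fold and *S100A4* 2.04-fold higher. With the first hybridization alone *PDGFRB* was not called (log2 fold change 0.92, adjusted p = 0.158), and the median of the fibroblast list was -0.08. Fry called the fibroblast list (adjusted p = 0.0266). Blood and macrophage markers gave 2 higher and 1 lower of 6, or 2 and 2 adjusted over the list alone (median 0.31, -0.14 with no filter, adjusted p = 0.769), with *LYZ* 1.19-fold higher and *CD74* 1.88-fold lower. Of the endothelial markers 4 were measured, too few to test, with 0 past the threshold, a median of -0.18, and *PECAM1* at -0.34 ± 0.24.

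For 24 named genes the call ended when 1 culture was left out, and for 20 of these VECELL 2 was such a culture. Without VECELL 2 alone the call ended for *CNN3* (log2 fold change -0.26, adjusted p = 0.0679 without it), *DNAJC3* (-0.59, 0.0608), *MDH1* (-0.20, 0.0802), *PHGDH* (-0.40, 0.0531) and *TUBB* (-0.19, 0.0604). Without VECELL 1 alone it ended for *ACOX2* (0.31, adjusted p = 0.0776) and *MAT1A* (-0.40, 0.0518), and without VECELL 3 alone for *RPL27A* (-0.49, 0.0541). Without VECELL 1 or VECELL 2 it ended for *HSPB1* (0.35, adjusted p up to 0.0531) and *RRP12* (1.39, and 0.87 without plate 1, up to 0.0523). Those 2 cultures and plate 1 each ended the call of *ACSL1* (-0.49, and -0.30 without plate 1, adjusted p up to 0.102), with plate 2 that of *CD3D* (1.25, up to 0.144), and with plate 3 those of *POLR1B* (-0.55, up to 0.0601) and *SLC2A2* (0.57, up to 0.0968). Without VECELL 2, VECELL 3 or plate 1 the call ended for *FBLN1* (-0.38, adjusted p up to 0.0686) and *SPARC* (-0.35, up to 0.136), and without VECELL 1, plate 1 or plate 3 for *TJP3* (-0.86, up to 0.0770). Without VECELL 1, VECELL 2, plate 2 or plate 3 it ended for *AEN* (-0.42, adjusted p up to 0.121). Any VECELL culture or 1 plate culture ended the calls of *CXCL8* (1.03, plate 3, adjusted p up to 0.120), *RXRA* (-0.42, plate 1, -0.27 without it, up to 0.149) and *UNG* (0.26, plate 2, 0.17 without it, up to 0.150). VECELL 1, VECELL 2, plate 1 and plate 2 each ended the call of *FGL1* (0.19, adjusted p up to 0.195), and with plate 3 also that of *IFIT1* (-1.14, and -0.67 without VECELL 1, up to 0.174). The call of *PES1* (0.44, and 0.29 without plate 2, adjusted p up to 0.140) ended without any culture but plate 1. Some of the calls in this paragraph also ended with the second hybridization alone, among them those of *RPL27A* (-0.09, adjusted p = 0.802), *CNN3* (-0.13, 0.424) and *TUBB* (-0.11, 0.448).

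For 28 named genes, *CYP3A4*, *CPT1A*, *ANGPTL4*, *SLC25A20*, *PDGFRB*, *PFKP* and *HSPG2* among them, the call held without any 1 culture but ended under another alternative. With the second hybridization alone it ended for *ATP8B1* (log2 fold change -0.38, adjusted p = 0.238), *HGD* (-0.23, 0.121), *IFI6* (-0.73, 0.0692), *NR2F6* (-0.27, 0.168) and *SLC7A11* (0.38, 0.0566). With the first alone it ended for *SLC30A1* (-0.31, adjusted p = 0.0996) and *UGDH* (-0.17, 0.167). With eBayes without the trend it ended for *HSPH1* (adjusted p = 0.0525), *MGST2* (0.0627), *MRTO4* (0.0620), *NDUFV2* (0.0545) and *S100A11* (0.0658). Without the trend or with the second hybridization alone it ended for *DLK1* (adjusted p up to 0.250), *LYZ* (up to 0.111) and *PROS1* (up to 0.180), and without the trend or with the first alone for *ATP7B* (up to 0.0586), *RPL39* (up to 0.205) and *RPL7* (up to 0.0812). The second hybridization alone and leaving out the 3 arrays with the highest medians each ended the calls of *GSTZ1* (adjusted p up to 0.227), *NPC1* (up to 0.119) and *TBX3* (up to 0.188). With the second hybridization alone the log2 fold change of *GSTZ1* was 0.37, against 0.59 with all arrays, and that of *TBX3* was 0.36, against 0.67. For *NPC1* it was 0.23 without the 3 arrays, against 0.42.

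Signs of RNA quality and labelling were compared between the vessels with exact permutation tests, in which the smallest p that 3 cultures against 3 allow is 0.1. The ratio of 3' to 5' signal of the actin control was 5.16 on the plate and 4.82 on VECELL (exact permutation p = 0.2), and that of GAPDH was 1.06 and 1.07 (p = 0.8). The 4 spike-in controls gave p between 0.2 and 0.7. Probe sets for ribosomal RNA were lower in all 3 VECELL cultures, with ratios of VECELL to plate of 0.758 and 0.766 for 28S and 0.892 for 18S (exact permutation p = 0.1 each). The median signal before normalization was lower in all 3 VECELL cultures as well, 94.7 against 103 on the plate. Between the first and second hybridization, limma with the culture as a block called 0 of 13329 probe sets, with 651 at an unadjusted p under 0.05.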

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

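The tests of array noise, metallothionein paralogs, MTF1 and normalization were chosen after the results they concern had been seen. So were the version of the hypoxia list without shared genes and the IL-6 test described under other observations. The other tests were written down before.

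The second array of VECELL culture 1 stood apart from the other 5 VECELL arrays, with a median log2 signal of 6.72 before normalization against 6.50 to 6.56. It was 1 of 10 sets of 6 arrays looked at for a lone value, of which chance picks out about 1 in 20. Among the array's control probe sets, which the comparison does not use, the actin controls were higher on VECELL, at ratios of 1.25 for the 3' and 1.34 for the 5' probe set. The GAPDH controls were also higher in all 3 VECELL cultures, at ratios of 1.10 and 1.09. The control for Alu repeats was lower in all 3 VECELL cultures, at a ratio of 0.850, and so was the ISGF3A control, at a ratio of 0.685.

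Of the 10 splits of the 6 cultures into 3 and 3, 1 called as many probe sets as the real one, which was the real split itself, with 2771 against at most 0 in the others. For gene lists the count was also 1, with 21 lists against at most 14. With 10 splits the share cannot go below 0.1, which is too few for a share under 0.05. The other splits mixed the vessels, so the vessel difference widened the spread within their groups and could keep their probe set counts low. Part of that difference also lay between their groups. Their counts therefore do not show what cultures without a vessel difference would give. For the hybridization rounds 32 of 32 assignments of arrays to rounds called at least the 0 probe sets of the real one. That share was fixed in advance, since no count can lie under 0, and decides nothing. The highest other assignment called 1.

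Hypoxia response genes rose on VECELL. Between-array normalization as the cause is argued against by the values as deposited or median centred, which gave medians of at least 0.71. The rise was seen in each hybridization round alone, with medians of at least 0.64. Every culture was in both rounds, so a round effect alone could not separate the vessels, and this check decides nothing about it. Lower oxygen around the cells is a candidate explanation: 22 measured hypoxia-induced genes in none of the lists, written down before their values were looked at, had a median of 0.40, with 14 higher and 2 lower (camera p = 1.65e-06, and p = 0.0143 with an estimated correlation). Without the genes shared with the glycolysis and ATF4 lists, 19 of 25 hypoxia genes rose and 0 fell (median 0.67, adjusted p = 9.32e-18). The same genes may respond to other activators of the pathway, and oxygen was not measured, so this stays a hypothesis.

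The 9 probe sets of the 6 metallothionein genes of the list rose, by 1.10 to 3.05 on the log2 scale, as did the related *MT1HL1* (2.40), while *MT3*, outside the list and picked after its values were seen, did not pass the test (0.21, adjusted p = 0.639). The probe set of *MT1HL1* is also of a kind that can match several transcripts, so its rise need not be that of a separate gene. How many of the genes changed cannot be told apart from 1 transcript read by several probe sets, because 0 genes had a probe set free of the suffixes that mark shared matches, which leaves that test without an outcome. A metal response through the factor MTF1 would be expected to raise the zinc exporter gene *SLC30A1* too. That gene changed by -0.36 (-0.31, adjusted p = 0.0996, with the first hybridization alone), so it did not rise. A single gene whose value had been seen beforehand cannot decide whether MTF1 took part. Other inducers of metallothioneins, glucocorticoids and low oxygen among them, were not tested.

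Cultures of 1 vessel differed about as much as 2 arrays of 1 culture, with a ratio of mean variances of 0.978 over all probe sets. An F test gave p under 0.05 in 5.28% of probe sets, where 5% is expected with no difference. No other pairing of a group's arrays gave a ratio above 1.10, which argues against wrongly assigned arrays hiding large differences between cultures. Differences smaller than the array noise would not show in this check, so it cannot exclude wrong assignment where cultures differ little. Array noise that hides differences between cultures cannot be excluded, although in the probe sets with a mean log2 signal of 12 and over, where arrays differ least, the ratio was 0.991. From 11 to 12 it was 1.07 with 8% of probe sets at p under 0.05, and from 10 to 11 it was 1.04 with 6.45%. Cultures that were not grown independently could give the same values, which the labels do not settle, and the adjusted p-values would then be too small for differences between independent cultures.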

How the results depend on the processing

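Leaving out the 3 arrays with the highest medians, and the hypoxia list without shared genes, were chosen after the data were seen. No called gene or list changed sign under any alternative run. Among those not called, 2 named genes (*MKI67* and *COL1A1*) did in 3 values and 9 lists in 32. For the 140 named genes past the threshold, 2177 of 2364 values under alternatives stayed past it in the same direction, 187 lost the threshold, and 88 genes kept it throughout. For the 21 called lists 444 of 461 values stayed, 17 did not, and 7 lists kept their call throughout. Of the named genes not past the threshold, 8 of 149 values passed it under an alternative, those of *ALB* and *AFP*, and of the 21 lists not called, 25 of 459 values were called, 13 of them with fry. The counts of probe sets higher and lower moved by more than 1.5 times with eBayes without the trend (783 and 630), the second hybridization alone (724 and 650), without VECELL replicate 2 (901 and 885), an adjusted p under 0.01 (827 and 738) and a 2-fold minimum (268 and 57), the last 2 being stricter thresholds and leaving out a culture giving fewer samples. For the others the cause was not tested. Leaving out each culture gave 901 to 1339 probe sets higher and 885 to 1249 lower, and 13 lists higher and 8 to 9 lower. With an estimated correlation 6 lists were called higher and 2 lower, and with fry 17 and 17. Without the 3 arrays with the highest medians 1065 probe sets were higher and 1050 lower, with 1920 of the original calls shared. Without the hypoxia genes shared with other lists the median was 0.67. Signal over background limits the weak genes: changes of probe sets with a mean log2 signal under 7 had a median SD between arrays of 1 culture of 0.639, against 0.0907 at 12 and over.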

Other observations

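The 4 gene groups of the next 2 paragraphs and the STAT3-driven acute phase genes were chosen after values had been seen. Their p-values describe these data and are not independent evidence. The IL-6 test on the whole acute phase and NF-kB list was also chosen after that list's values had been seen. The test of further BMP-SMAD targets was written down before.

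In a group of S100 proteins and annexins, which also held *S100PBP*, whose product binds the protein S100P but is neither, 11 of 19 genes were higher and 2 lower on VECELL (median 0.80, adjusted p = 9.67e-07 over the 4 groups, and 0.0121 with an estimated correlation). *S100P* was 2.15-fold and *S100A10* 1.98-fold higher, while *ANXA9* was 1.59-fold lower. The group shares *S100A4*, *S100A6*, *S100A10*, *S100A11*, *ANXA2* and *ANXA3* with the mesenchymal list. Keratin genes gave 4 higher and 0 lower of 6 (median 0.49, adjusted p = 1.12e-05, and 0.0123 with an estimated correlation), with *KRT23* 4.46-fold, *KRT18* 1.41-fold and *KRT8* 1.39-fold higher.

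Genes of MHC class I and antigen processing gave 11 lower and 0 higher of 15 (median -0.36, adjusted p = 2.58e-06, and 0.0123 with an estimated correlation). The peptide transporter gene *TAP2* changed by -0.59 on the log2 scale, and *HLA-B* was 1.33-fold and *B2M*, the shared light chain, 1.23-fold lower. Of 7 BMP-SMAD targets, *HAMP* among them, 6 rose and 0 fell (median 0.56, adjusted p = 6.21e-08, and 0.0121 with an estimated correlation), with *ID2* 1.48-fold and *BAMBI* 1.38-fold higher. All of them but *HAMP* also belong to the TGF-beta list.

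Hepcidin is induced by BMP-SMAD signalling and by IL-6 through STAT3, and both were put to a test. BMP-SMAD signalling may contribute, but 6 further targets in none of the groups above did not decide it: their median was 0.61 with 1 gene higher, *HEY1* (p = 0.0931, and 0.160 with an estimated correlation). An IL-6 response was left open as well, since the acute phase and NF-kB list gave 4 higher and 6 lower and was not called (median -0.20, adjusted p = 0.152). Its 7 STAT3-driven genes had a median of -0.55 with 0 higher and 5 lower, but they were picked after their values had been seen and decide nothing here.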
